A study of Drosophila melanogaster with 4 samples.

How the data were processed

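RNA from whole adult males of the Drosophila melanogaster strain dp cn bw cl, 6 to 7 days after eclosion, was compared on 2-colour cDNA arrays, per the labels. Cold-shocked flies were held for 2 h at 0 ± 0.5 °C and then for 30 min at 25 °C, and their co-reared controls stayed at 25 °C. Total RNA was extracted with TRIzol and labelled directly, per the labels' protocols. There were 4 arrays. On 3 arrays of the 12k design, each carrying one of the independent biological pairs, cold-shocked RNA was in Cy5 and untreated RNA in Cy3. On 1 pilot array of the 7k design the dyes were the other way round.

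The deposited values are 1 log ratio of the channels per spot, derived by the authors from normalized data, per the labels. The image analysis, the background correction, the normalization method and any filter on spots are not given in the sources used here. The base of the logarithm is not stated either. It was taken as log2 by elimination, and all folds given here depend on that. Values reached −14.57 on array 1 of the 12k design and −12.29 on the pilot array, while the natural log of the full range of a 16-bit scanner is 11.09. This limit assumes channel values of at least 1 after processing, which was not checked. The deposited log2 ratios were used without further centring, and the array medians were −0.13, 0.03 and 0.03 on 12k arrays 1 to 3 and 0.40 on the pilot. Channel intensities were not analysed here, so no spot could be judged against background.

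The direction of the ratio is not stated. For the 12k arrays, Cy5 over Cy3, channel 2 over channel 1 and treated over control all mean cold-shocked over untreated, so a positive ratio is likely higher in cold-shocked flies. For the pilot these conventions disagree, and its direction is not settled. Since the 12k arrays share a single dye orientation, a dye effect and a treatment effect cannot be separated on them.

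Spots were named through the platform annotation. Of 27648 spots on the 12k design, 15116 had 1 gene symbol, 102 had several and 12430 had none, which gave 6793 named genes. Of 16896 spots on the 7k design, 5666 had 1 symbol, 152 had several and 11078 had none, which gave 2377 named genes. Gene identifiers of 14894 named 12k spots were found in the RefSeq table of the Release 6 assembly and 222 were not, and those kept the annotation's name. No coordinates are given, because the sources used here name no genome build for the arrays. A spot with several symbols, which includes spots shared by near-identical Hsp70 genes, was not named.

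Spots of one gene were averaged within an array, and every spot without a single symbol was kept as its own feature, which gave 19325 features, all with a value on all 3 arrays. The mean log2 ratio was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual and 4.99 prior degrees of freedom. Features past a fold of 1.5 in one direction on all 3 arrays were also counted, beside 100 draws in which features were shuffled within each array. The 22 gene lists with at least 3 measured members, out of 23 written down beforehand, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The lists covered heat shock, cold, early response, chaperone, proteasome, energy, sugar, lipid, detoxification, immune, ion transport and circadian genes, ribosomal proteins, and markers of the tissues of whole flies, including female ones. Many members were not measured on the 12k design, which held 5 of 20 heat shock, 8 of 25 female, 6 of 43 immune and 16 of 80 ribosomal genes. Of the cold list it held 5 of 5. The cold list was recalled from published work that may include this study. The pilot, a single array, was compared gene by gene and with no p-value, and its list medians were placed among 10000 random lists of the same size. These lists were not matched on expression, for want of intensities.

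The genes named are the 10 in each direction with the smallest unadjusted p and one sign on all 3 arrays, the rule fixed for the case that fewer than 5 pass in a direction. Added to these are the 3 members of each list with the largest absolute mean log2 ratio and all measured members of the heat shock and cold lists. The lists, tests, naming rule and the other settings listed first below were fixed before the data were examined.

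The fit was tested on simulated data of 19325 features on 3 arrays with 200 changed features. It recovered 0% of them at a fold of 2, 81.6% at a fold of 4 and 98% at a fold of 8. Simulated noise was unrelated between features, unlike that of neighbouring spots on the arrays, and all changed features had one fold. These shares may therefore be too high for the data. They also hold only for 200 changed features, since the Benjamini-Hochberg cut-off is stricter when fewer features stand out. In the data dhd, 5.19-fold lower on average, did not pass. The number of arrays limits the precision. The alternatives were median centring, a common scale, spots tested singly or by their median, removal of genes with disagreeing spots, a robust variance model, a test against a fold of 1.2, other thresholds and folds, omission of each array, and addition of the pilot. After the data had been seen, 4 more were added. These were named genes only, subtraction of the median of the 7 by 7 spots around each spot within inferred print blocks of 24 by 24, averaging of unnamed spots as printed pairs, and omission of repeated values. Figures were drawn with matplotlib 3.10.9.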

Results

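The series addressed how transcript levels in adult male fruit flies differ after a cold shock. Each of 3 arrays of the 12k design compared cold-shocked males with untreated males from an independent biological pair, and 1 pilot array of the 7k design made the same comparison with the dyes reversed. The values were the authors' log ratios per spot, taken here as log2. On the 12k arrays a ratio above 0 is likely higher in cold-shocked flies, because Cy5 over Cy3, channel 2 over channel 1 and treated over control all point that way. The files used here do not state it.

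The SD of the log2 ratios over all spots was 0.729, 0.457 and 0.697 on 12k arrays 1 to 3 and 0.721 on the pilot. Each odd spot and the next even one were taken as a printed pair, which carried 1 gene in all 7558 pairs with names on the 12k design. Across spots, the rank correlation within printed pairs was 0.462, 0.274 and 0.435 on the 12k arrays and 0.884 on the pilot. The next spot over, from another printed pair, correlated at 0.337, 0.223 and 0.344 on the 12k arrays and at 0.283 on the pilot. After subtraction of local medians, printed pairs on the 12k arrays correlated at 0.239, 0.219 and 0.293 and neighbouring spots at 0.0610, 0.158 and 0.183. Across the 6793 named genes, which are not independent replicates, Pearson's r was 0.0878 between arrays 1 and 2, 0.0983 between arrays 1 and 3 and 0.0782 between arrays 2 and 3. Spearman's rho for the same pairs was 0.0837, 0.116 and 0.0754.

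**Figure D1:**
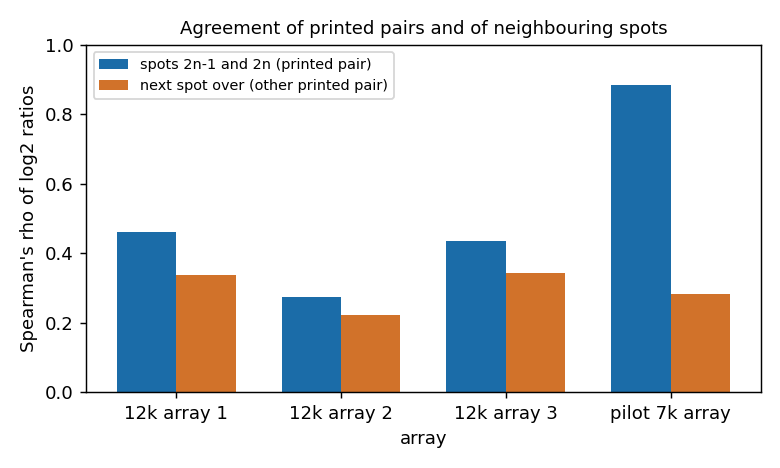
Spearman's rho of the deposited log2 ratios on each array (vertical axis, no unit), across printed pairs (blue bars) and across neighbouring spots of different pairs (orange bars). Printed pairs reach 0.884 on the pilot and at most 0.462 on the 12k arrays, where neighbouring spots reach 0.344.

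Of the named genes with the smallest unadjusted p, Yp1 and dhd had the lowest mean ratios and CG5550 the highest. Yp1, which encodes a yolk protein, had a mean log2 ratio of −2.64 ± 1.44 (SD, n = 3), a level 6.25-fold lower in the cold-shocked channel. The gene dhd, which encodes a germline thioredoxin of the oocyte, stood at −2.38 ± 0.55 (n = 3), or 5.19-fold lower. The engulfment receptor gene drpr followed at −1.93 ± 0.81 (n = 3). On the other side, CG5550 stood at 1.35 ± 0.08 (n = 3), or 2.56-fold higher, and the cold-recovery gene Fst (Frost) stood at 1.03 ± 0.40 (n = 3), or 2.04-fold higher. Each of these genes had the same sign on all 3 arrays, and none passed the test, with a limma adjusted p of 0.853 for each.

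Of 19325 features, 0 passed limma's test at an adjusted p of 0.05, and the smallest adjusted p was 0.853. At an unadjusted p of 0.05 there were 924, of which 287 were higher and 637 lower, against 966.25 expected by chance. Subtraction of the local median around each spot, an alternative chosen after seeing the data, moved this split to 463 higher and 545 lower. Among the 6793 named genes 237 were under that unadjusted p, 62 higher and 175 lower, against 339.65 expected. Fitted alone, an alternative also chosen after seeing the data, the same genes gave 387, 112 higher and 275 lower, above that expectation. The smallest limma adjusted p was then 0.184. The fit to all features shares a variance prior between named genes, averaged over their spots, and unnamed single spots. The count of 237 therefore does not show fewer changes than expected by chance.

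The other genes with high ratios and the smallest unadjusted p were CG10912 at 1.25 ± 0.35, CG8778 at 1.21 ± 0.26, CG10383 at 1.02 ± 0.49, ghi at 1.00 ± 0.10 and CG9568 at 0.99 ± 0.40 (SD, n = 3). CG18609, CG44251 and CG8197 had means of 0.99, 0.86 and 0.83. The low side held CG12025 at −1.40 ± 0.74, the splicing factor gene Cwc25 at −1.31 ± 0.73, hec at −1.18 ± 0.56, CG15186 at −1.16 ± 0.53 and mmm at −1.15 ± 0.31 (SD, n = 3). Naprt, which encodes an enzyme of NAD synthesis, had a mean of −1.11 and WDR79 one of −1.07. None of these genes passed the limma test. With local medians subtracted, CG12025, Cwc25, hec, CG15186 and Naprt had means of −0.40, −0.84, −0.47, −0.38 and −0.22, while the means of the other 15 of these 20 genes stayed within 1.5 times. Spots of one gene differed by over 2 in log2 on at least 1 array for 11 of the 89 genes chosen by the naming rule, so their means are uncertain. These are Cwc25, tim, CCT1, CCT3, Cyp6a8, Ald1, DnaJ-1, Obp84a, Obp56e, RpS20 and Tps1.

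**Figure D2:**
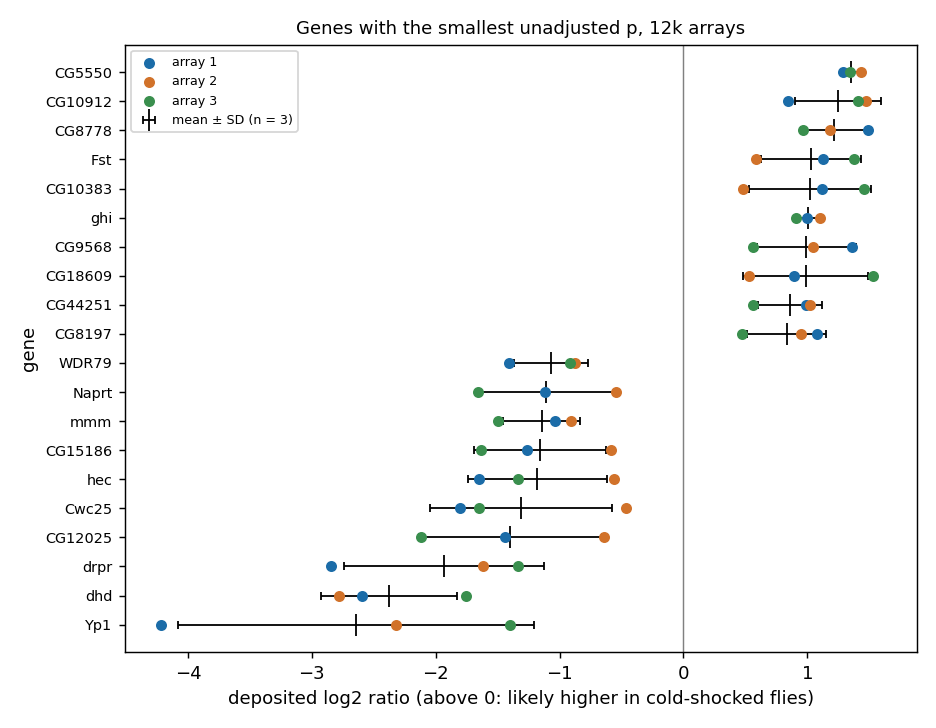
Deposited log2 ratio (horizontal axis) of the 20 named genes with the smallest unadjusted p and one sign on all 3 arrays of the 12k design. Coloured points are single arrays and black bars the mean ± SD (n = 3). Yp1 spans −4.22 to −1.40, while the values of CG5550 lie between 1.29 and 1.44.

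Counted by size alone, 86 features lay past a fold of 1.5 in one direction on all 3 arrays, 33 higher and 53 lower. Shuffled features gave a mean of 47.2 and at most 61 over 100 draws, while turning the sign of array 2 gave 84. Among them were 15 named genes, where shuffling gave a mean of 6.75 and at most 13. The 5 higher ones were CG5550, CG10912, CG8778, Fst and ghi. The 10 lower ones included Yp1, dhd, drpr, CG12025, mmm and WDR79. Of the 10, salt, Gdap1, CG5704 and eIF2D were outside the naming rule and are named after their values were seen, and stood 1.61-fold, 1.62-fold, 1.67-fold and 2.00-fold lower on average. With local medians subtracted the count of features was 57, against a mean of 25.6 when shuffled in that setting. Shuffling breaks the correlation of printed pairs and of neighbouring spots, so its maximum may be too low. With unnamed spots averaged as printed pairs the count was 28, against a mean of 14.3 when shuffled. Of all features 27.8%, and of the named genes 29.4%, had one sign on all 3 arrays, where chance gives 25%.

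Heat shock genes had ratios above 0 for 3 of 5 measured members, out of 20 on the list. Hsp68, an inducible member of the Hsp70 family, had a mean log2 ratio of 0.83 ± 0.95, the small heat shock protein gene Hsp26 one of 0.82 ± 0.62, and the co-chaperone gene stv one of 0.55 ± 0.13 (SD, n = 3). Hsp26 and stv were above 0 on all 3 arrays. Hsp68 was at −0.07 on array 3. The remaining members were l(2)efl at −0.36 ± 0.99 and DnaJ-1 at −0.16 ± 0.36 (SD, n = 3), with means of −0.0218 and 0.0439 when local medians were subtracted. No member passed over all genes, and 0 passed when adjusted over the list alone, where the smallest limma adjusted p was 0.0960. The list had a camera p of 0.0231 and an adjusted p of 0.254 (adjusted p = 0.946 with an estimated correlation), so it did not pass. Without array 3 its adjusted p was 0.00661, in a range up to 0.986 over the other settings, and Hsp26 and Hsp68 then passed over the list alone.

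Of 5 measured genes on the cold list, CG10912 and Fst were higher on all 3 arrays, with the values above. CG12164 was lower on all 3, at −0.34 ± 0.27, while CG16743 at −0.71 ± 0.90 and smp-30 at −0.17 ± 0.23 had mixed signs (SD, n = 3), with −0.45 and −0.0311 after subtraction of local medians. CG10912 and Fst passed when adjusted over the list alone, with limma adjusted p of 0.00684 and 0.0114, and not over all genes. This is not independent evidence, because the list may draw on this study. Neither passed over the list alone without array 3. The list as a whole had a mean of 0.21, a median of −0.17 and a camera adjusted p of 0.763. For change in either direction, fry gave a p of 0.00789 and an adjusted p of 0.174.

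Markers of females, listed because whole flies could be mis-sexed, were lower for 6 of 8 measured members. The yolk protein genes Yp1, Yp3 and Yp2 had means of −2.64, −0.99 and −0.79, and osk, which patterns the oocyte, one of −0.45. All 4 were below 0 on all 3 arrays. The largest contribution came from array 1, where Yp1, Yp3 and Yp2 stood at −4.22, −1.78 and −2.06. The members swa at 0.16 and fs(1)N at 0.25 lay above 0, and yl at −0.22 and otu at −0.18 below, each with mixed signs over the arrays. Yp1 passed when adjusted over the list alone, with a limma adjusted p of 0.00860, and no member passed over all genes. The camera p for the list was 0.00796 and the adjusted p 0.175 (adjusted p = 0.946 with an estimated correlation). Without array 3 the adjusted p was 0.0208, in a range up to 0.946 over the other settings.

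Of the 69 named genes outside the 20 with the smallest p, 50 had means that shrank by over 1.5 times or turned without one array. Among them were Yp2, Yp3 and Hsp68 at −0.16, −0.59 and 0.33 without array 1, and GstE2, LManVI and Tps1 at −0.44, −0.36 and −0.28 without it. With local medians subtracted this held for 31 of all 89 named genes.

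Over the 22 lists tested, 0 passed with camera, with either correlation, or with fry, where the smallest adjusted p was 0.855 for a shift in one direction and 0.174 for change in either. With camera, 2 lists had an unadjusted p under 0.05, the female markers and the heat shock genes, and with an estimated correlation 0 did. Over the list alone 3 genes passed in all, in 2 lists. About 1.1 of the 22 lists would hold such a gene by chance.

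Early response and JNK pathway genes included 4 of 11 members above 0 on all 3 arrays and 0 below on all 3. The Fos gene kay had a mean of 0.72 ± 0.37, CG14186 one of 0.68 ± 0.28 and the ETS factor gene Ets21C one of 0.37 ± 0.19 (SD, n = 3), which became 0.0456 with local medians subtracted. The list mean was 0.14 and the camera adjusted p 0.454, and 0 members passed over the list alone. No turandot gene, of a family of secreted stress proteins, could be tested as a list, with 2 measured members. TotF stood at −0.47 and TotB at −0.11.

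**Figure D3:**
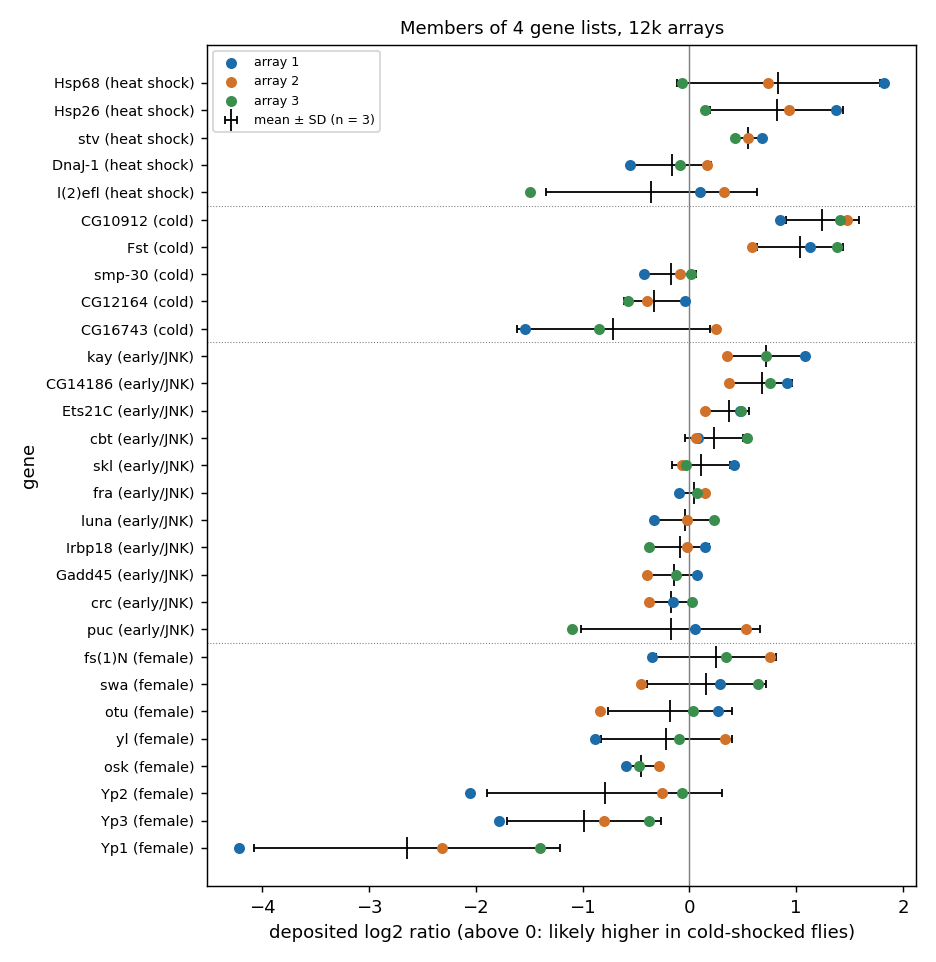
Deposited log2 ratio (horizontal axis) of every measured member of the heat shock, cold, early response and JNK, and female marker lists on the 12k arrays. Coloured points are single arrays and black bars the mean ± SD (n = 3). Fst, CG10912, kay and stv lie above 0 on all 3 arrays, and Yp1, Yp2, Yp3 and osk lie below.

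Lists of protein turnover and translation had means close to 0. The 20 measured proteasome genes had a mean log2 ratio of 0.04, the 15 constitutive chaperone genes one of −0.05 and the 16 ribosomal protein genes one of 0.03. Rpn5 stood at −0.58, with one sign on all 3 arrays, and Rpn7 at 0.63, set by array 1, without which it was 0.11. RpS20, with a mean of 0.68, ranged from −0.83 to 2.60 over the arrays. CCT3, of the chaperonin that folds actin and tubulin, had a mean of −0.57, and of −0.0693 with local medians subtracted.

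Energy, sugar and lipid genes also gave small means, of 0.02 for both glycolysis and the TCA cycle with oxidative phosphorylation, −0.02 for sugar, polyol and proline metabolism and 0.05 for membrane lipid genes. Tps1, which makes trehalose, stood at −0.57 ± 0.55 and the desaturase gene CG9747 at −0.63 ± 0.47 (SD, n = 3), both lower on all 3 arrays. SdhB had a mean of 0.36 and Pgk one of −0.36, or 0.17 and −0.0769 with local medians subtracted.

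Detoxification genes had a mean of −0.04, with GstE2 at −0.99 ± 0.96 (SD, n = 3) and Cyp6a8 at −0.48, each below 0 on all 3 arrays, though GstE2 was at −0.0596 with local medians subtracted. Immune effector genes had a mean of 0.10, with the serpin gene nec at 0.70 ± 0.46 (SD, n = 3), or 0.45 with local medians subtracted. Ion transport genes had a mean of −0.09, and the aquaporin gene Drip was lower on all 3 arrays, at −1.02 ± 0.46 (SD, n = 3). Circadian genes had a mean of −0.0050, and tim, a core clock gene, stood at −0.59 ± 0.42 (SD, n = 3).

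Tissue markers showed no list past the test. The means were −0.11 for midgut digestive genes, −0.17 for odorant binding proteins, −0.05 for fat body, −0.03 for eye, 0.04 for muscle and cytoskeleton, 0.08 for the male accessory gland and 0.0022 for testis. Among their members, the midgut protease gene Jon25Bi stood at −0.56 ± 0.23, the mannosidase gene LManVI at −0.81 ± 0.79 and the testis proteasome gene Prosalpha4T1 at −0.62 ± 0.18 (SD, n = 3), each lower on all 3 arrays. With local medians subtracted Prosalpha4T1 was at −0.16 and CG5966 of the fat body list, with a mean of −0.50, at −0.0904. Obp84a had a mean of −1.47, set by −4.39 on array 3. The means were −0.53 for rdgA of the eye list, 0.49 for Mlc2 of muscle and 0.17 for Acp53Ea of the accessory gland. Over the 18 lists other than the female, heat shock, cold and early response ones, camera adjusted p was at least 0.763. The camera test, which sets a list against all other features, was upward for the detoxification, sugar, constitutive chaperone and circadian lists although their means were below 0. The ion transport and detoxification medians were above 0 with means below, and the glycolysis median below with its mean above.

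The pilot array asked the same question with reversed dyes. Its direction is not settled, so its values are given as deposited, relative to the array's median of 0.40, and all would change sign if the ratio ran the other way. There was no replicate. Hsp68 stood at 1.05, DnaJ-1 at 0.66 and stv at 0.39 above that median, CG14186 at 0.91 and CCT1 at 1.21, while CG5966 stood at −1.57 and kay at −0.17. Among lists, the median of 18 odorant binding genes lay at the 98.1 percentile of 10000 random lists and that of 3 heat shock genes at the 92.9 percentile. The lowest were TCA and oxidative phosphorylation at 1.22, fat body at 1.78 and sugar, polyol and proline metabolism at 2.61, with 3, 5 and 6 members.

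Across the 1823 genes on both designs, the pilot and the mean of the 12k arrays had a Pearson's r of −0.113 and a Spearman's rho of −0.127 with the sign as deposited, and an r of 0.113 with the pilot turned. Genes are not independent replicates here. Against single 12k arrays r was −0.0564, −0.0129 and −0.126. Drip, hec and GstE2, which were lower on all 12k arrays, stood at 0.96, 0.98 and 0.63 above the pilot's median. CG5966, CG9747 and Naprt, also lower on all of them, stood at −1.57, −0.60 and −0.08 against it. With local medians subtracted, the 12k means of hec, GstE2, CG5966 and Naprt were −0.47, −0.0596, −0.0904 and −0.22. Hsp68 and CG14186 had the same sign on the pilot as in their 12k means.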

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

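The count of changed genes was 0 under all 17 alternatives that could be run, with a smallest adjusted p from 0.184 for named genes only to 1.00 for the test against a fold of 1.2. The filter on missing values was not run, because no value was missing. No paired analysis was possible because each 12k ratio already compares a pair within its array and the pilot is a group of 1 array. Named genes only, local median subtraction, printed pairs and removal of repeated values were chosen after seeing the data.

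Of 86 features past a fold of 1.5, there were 450 at a fold of 1.3, 7 at a fold of 2, 177 with every spot its own feature, 57 with local medians subtracted, 15 for named genes only, 28 with unnamed spots averaged as printed pairs, and 407 to 912 without one replicate, where only 2 arrays had to pass. The 924 features at an unadjusted p under 0.05 became 335 with the fold of 1.2, 387 for named genes only (fewer tested, though 237 of the same genes were under it in the fit to all features), 597 without replicate 3, and 55 or 138 of 1823 with the pilot added as deposited or turned. The split of 287 higher and 637 lower became 505 and 512 without replicate 1 and 204 and 1004 without replicate 2. The number of lists past the test, 0, ranged from 0 to 2 without one replicate.

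The correlation with the pilot became 0.113 with its sign turned, by construction, and −0.0129 with replicate 2 in place of the mean. With local medians subtracted, 31 of 89 named genes had means over 1.5 times smaller or turned, among them Naprt at −0.217, CG15186 at −0.377, CG12025 at −0.395, hec at −0.466, GstE2 at −0.0596 and Prosalpha4T1 at −0.156. DnaJ-1 became 0.0439, Acp53C14a −0.0613 and the shift of the sugar, polyol and proline list against all features −0.000306. The cause was not tested. Without one replicate, mean log2 ratios ranged from −0.767 to 0.0379 for CCT1, −0.580 to 0.0109 for trp, −0.323 to 0.0365 for DnaJ-1, −0.0141 to 0.262 for Acp53C14a, −0.279 to 1.44 for RpS20, −0.181 to 0.820 for RpLP1, −0.162 to 0.733 for Pdf, −0.698 to 0.212 for l(2)efl, −0.459 to 0.0250 for LysE, −0.317 to 0.775 for Inx7, −0.00187 to 0.367 for Acp32CD, −0.00276 to 0.611 for Mlc-c and −0.452 to 0.0933 for ATPsynD. List shifts ranged from −0.0486 to 0.209 for circadian, −0.00925 to 0.0181 for constitutive chaperones, −0.0322 to 0.0566 for detoxification, −8.7e-05 to 0.0407 for eye, −0.0732 to 0.0627 for fat body, −0.188 to 0.0244 for odorant binding and −0.0263 to 0.113 for sugar, polyol and proline genes. The 3 genes passing over the list alone became 4 with median centring, with local medians, for named genes only and without replicate 2. They remained 3 without replicate 3, of which only Yp1 was shared. Signal over background could not be judged, because intensities were not analysed here.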

Other observations

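All tests in this part were chosen only after the results they bear on had been seen, at least in part, and the set of Yp1, Yp2, Yp3 and dhd was picked from its values.

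Yp1, Yp2, Yp3 and dhd, genes known from females although the flies are labelled male, had a mean log2 ratio of −1.70, with −2.66, −1.54 and −0.90 on arrays 1 to 3. The tables argue against a wide trend around these spots as the whole cause, since 92.3% of this mean remained after subtraction of local medians. A defect covering only the 2 spots of a gene would pass this step, and was not tested. For arrays 2 and 3 the test of female flies in the untreated samples was whether the median of ovary genes reached −0.5. There 22 other ovary genes had a median of 0.10, above that bound (95% interval −0.112 to 0.174 by a bootstrap over genes). Genes on an array are not independent replicates of fly samples. Of the 22 genes, 17 were outside the female list. The lower ratios of Yp1, Yp2, Yp3 and dhd, with a mean of −1.22 on these arrays, were not shared by this set as a whole. This holds only as far as spots above background were measured. The bound was not derived from a share of females, so the test cannot say what share of females it would exclude. On array 1 female flies stay open, with a median of −0.285 (−0.722 to 0.126) and 10 of the 22 genes at −0.5 or lower, against 21.7% of all named genes. The median of all named genes there was −0.116, and the ovary median lay at the 6.81 percentile of random lists of the same size. A single array also stays open. The mean was −1.22 without array 1, and for Yp2 and Yp3 alone it was then −0.377, short of the bound of −0.5. Yp2 and Yp3 were named through the female list and not for a small p, but they belong to the set picked from its values. An effect of cold in males and a dye effect were not tested.

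On the 12k arrays neighbouring spots of different genes had related ratios. A candidate explanation is local background on the slide, as side by side spots correlated more than spots 12 columns apart on all 3 arrays, by at least 0.227. After subtraction of local medians the neighbour correlations were 0.0610, 0.158 and 0.183, so a part was left whose cause was not tested. No biological explanation was tested.

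The pilot and the 12k arrays ran against each other across genes. Of 70 genes with an unadjusted p under 0.05 on the 12k arrays, 32.9% had the same sign on the median-centred pilot as deposited (95% interval 21.2 to 44.1 by a bootstrap over 48 inferred print blocks) and 67.1% with the pilot turned, and of 572 genes with one sign on all 3 arrays 42.7% (38.2 to 47.4) and 57.3% did. A dye effect, with the pilot ratio running as cold-shocked over untreated, may give this, and so may a treatment effect with the ratio running the other way. What the first needs was seen, since all 3 heat shock genes on the pilot lay above its median, the sign of the list mean over the 12k arrays. This is weak ground, as that list did not pass its test and its mean was −0.22 on array 3. The second explanation needs the heat shock genes below the pilot's median, which was not seen, on the same weak ground. This explanation stays open, because gene by gene 2 of 3 had the sign of their 12k mean, short of the 3 set to exclude it, on 1 pilot array. The exception was DnaJ-1, whose 12k mean of −0.16 became 0.0439 with local medians subtracted.

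Turning the sign of one array at a time gives 4 patterns of the 3 arrays, too few for a share under 0.05. As deposited, 924 features had an unadjusted p under 0.05, and the highest of the other patterns gave 822, so 1 of the 4 patterns gave as many. For features past a fold of 1.5 on all 3 arrays the values were 86 and 84, again with 1 of 4 patterns giving as many. Among named genes fitted alone the values were 387 and 248, and for the fold count 15 and 8.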
